A study of Mus musculus with 25 samples.

How the data were processed

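RNA from the pituitaries of 25 hypogonadal mice was measured by sequencing of polyadenylated RNA. These mice, called hpg, carry a deletion in the gene for gonadotropin-releasing hormone (GnRH) and make none of it. Per the labels' protocols, animals received 1 µg GnRH or saline by intraperitoneal injection once a day for 10 days and were killed 1 h after the last injection. Per the labels' protocols, ribosomal and globin transcripts were depleted during library preparation, and RNA integrity numbers lay above 8.2 with a median of 9.1. The groups were 5 placebo females, 6 GnRH females, 6 placebo males and 8 GnRH males, numbered 1 to 25 as in the labels. The series' design text speaks of 5 to 7 replicates per condition, whereas the labels of the samples place 8 animals in the male GnRH group, and the labels were followed. No number is shared between groups, and no paired analysis was possible because nothing in the labels pairs the animals.

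The deposited table holds regularized-log values, per the name the authors gave it, which are log2 values that were scaled between libraries and shrunken towards each gene's mean before deposit. Shrinkage is strongest for genes with few reads, so differences of low genes are understated, and a fold computed from these values is a fold on that scale. Per the submitters' processing notes, bcl2fastq, STAR, featureCounts and the mouse build mm10 were used, and their versions, the strand setting and the gene annotation are not given in the sources used here. No counts were analysed here, so the depth of each library is unknown and no counting interval was computed. The submitters state that access to the raw data was lost.

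The table had 47069 genes, of which 13765 were at 0 in all 25 libraries. Values ran from -2.34 to 21.92. Genes with a mean of at least 3 were tested, which left 19141. Correlations between any 2 libraries lay between 0.992 and 0.998, and the highest share of equal values between 2 libraries was 0 percent of the genes tested. The medians of the libraries lay between 8.09 and 8.13. No batch or date is given in the sources used here.

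The comparisons were fitted with limma 3.58.1 in R 4.3.3. A single linear model with 1 mean per sex and treatment group was fitted to all 25 libraries, with 21 residual degrees of freedom and a moderated variance that followed a trend on the mean. The 6 contrasts were GnRH against placebo in females, the same in males, the difference between these effects, males against females within placebo and within GnRH, and the GnRH effect averaged over the sexes. Tests were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Any adjusted p in the text comes from limma unless another test is named. On simulated data with the spread of the real genes, the test recovered 92% of genes changed by 0.5 on the log2 scale in the female contrast and 96% in the male contrast, and 100% of those changed by 1 or more. Unchanged genes made up 6.67% of the simulated calls in females and 5.26% in males. The simulated noise was independent between genes and animals, with a single SD per gene for all groups. The 200 changed genes were drawn at random from all genes tested. The rates therefore need not hold for genes with a wide spread, or where fewer genes change. Correlation between genes and unequal spread between groups were not simulated, so these rates may not carry over to the real data.

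The 25 gene lists cover gonadotropes, immediate early genes, AP-1 and ATF subunits, feedback inhibitors of MAP kinases, GnRH signalling, the activin and BMP pathway, the unfolded protein response, secretory granules, steroid response, glucocorticoid response, proliferation, cholesterol synthesis and sex-linked genes. They also cover somatotropes, lactotropes, thyrotropes, corticotropes, melanotropes, stem cells, the posterior lobe, endothelium, pericytes and fibroblasts, macrophages, blood and mitochondrial transcripts. Of 313 members, 311 had a row and 304 were tested; Kiss1 had none, and 2 members were found under older symbols, Cyr61 and Ctgf. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists within each of 5 contrasts, and again with an estimated correlation and with fry. Some genes sit in more than 1 list.

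The genes named were fixed by rule. They are 8 genes whatever their values (Atf3, Fshb, Lhb, Cga, Gnrhr, Fos, Jun, Egr1), up to 10 with the largest differences in each direction among those past the threshold, leaving out predicted genes and pseudogenes, and up to 4 members of each list by smallest p. In the sex contrasts up to 6 genes per direction were taken. Genes outside the rule are said to be so where they appear. The 4 groups, lists, tests, naming rule and most alternative settings were chosen before the data were examined. For the 8 genes, exact two-sided permutation tests within each sex were run beside limma. Relations across GnRH-treated animals used Pearson's r and Spearman's rho with exact permutation tests. Alternatives covered the filter, scaling, variance model, library weights, covariates for dissection and blood, the libraries in the fit, the set test, and leaving out each library in turn. A count-based alternative was not run, since no counts were at hand. Each count was also compared with the counts of 100 splits of the same samples. Positions come from GENCODE M21 on GRCm38, the assembly also called mm10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.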

Results

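Gene expression was measured in the pituitaries of 25 hpg mice, which lack GnRH, after 10 days of daily GnRH or placebo injections and 1 h after the last of them. The series asks, by its title, about the transcription factor ATF3 and follicle-stimulating hormone (FSH), so Atf3 and Fshb lead the account. The design crossed sex with treatment, with 5 placebo and 6 GnRH females and 6 placebo and 8 GnRH males. Each animal gave 1 library, and values are on the regularized log2 scale. The depth of the libraries is unknown. No group had a single injection or a later time point. Effects of the last dose, of repeated dosing and of indirect routes therefore cannot be told apart.

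GnRH against placebo in females asked which transcripts differ after repeated GnRH in animals that had none of their own. Fshb, the beta subunit of FSH, was 4.20-fold higher with GnRH. Its mean was 9.77 ± 0.53 (SD, n = 5) in placebo and 11.84 ± 0.56 (SD, n = 6) in GnRH females, a log2 difference of 2.07 (SE 0.27, adjusted p = 0.000347), and 6 of 6 treated animals lay above every placebo animal. Rrad, a small GTPase that restrains calcium channels, rose by 2.26 (SE 0.43, adjusted p = 0.0245). The neurofilament subunits Nefm and Nefl rose by 1.01 and 0.95, with adjusted p = 0.0197 and 0.000279. The protease inhibitors Serpinb1a and Timp1 rose by 1.06 and 0.79, with adjusted p = 0.0258 and 0.0363. Tnfrsf12a, a receptor of the TNF family, and Scarb1, the receptor for high-density lipoprotein, each rose by 0.81, with adjusted p = 0.0111 and 0.00421. The transcriptional coregulators Cited4 and Sertad1 rose by 0.77 and 0.69, with adjusted p = 0.00204 and 0.0175. All of these were above every placebo animal in 6 of 6 treated females, apart from Nefm with 5 of 6.

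In all, 19 of 19141 genes passed in females, 19 higher and 0 lower, against 1831 genes at an unadjusted p under 0.05, where 957 would come by chance. The 147 genes whose groups did not overlap compare with 82.9 by chance. The count fell to 7, 5, 4, 12 and 6 without placebo animals 3 and 5 and GnRH animals 6, 7 and 11, and rose to 67 without GnRH animal 10. Fshb, Nefl, Scarb1 and Cited4 passed in each of the 11 fits that left out 1 female, whereas Rrad lost its call in 9 of them, Timp1 in 10, Nefm and Serpinb1a in 7 each, Sertad1 in 3 and Tnfrsf12a in 1.

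Atf3, a stress- and signal-induced factor of the ATF family, had a log2 difference of 1.98 (SE 0.51) in females that missed the threshold across genes (adjusted p = 0.135). Its mean was 6.20 ± 0.11 (SD, n = 5) in placebo and 8.18 ± 1.00 (SD, n = 6) in GnRH females. All 6 treated animals lay above every placebo animal, and the exact two-sided permutation test of this gene alone gave p = 0.00433. Without GnRH animal 10, whose Atf3 of 6.55 was closest to placebo, the difference was 2.30 (adjusted p = 0.0275). Lhb, the beta subunit of luteinizing hormone, differed by 0.45 (adjusted p = 0.207), Cga, the alpha subunit both hormones share, by 0.49 (adjusted p = 0.355), and Gnrhr, the GnRH receptor, by 0.59 (adjusted p = 0.221). The immediate early genes Fos, Jun and Egr1 differed by -0.39, 0.21 and 0.10, with adjusted p = 0.721, 0.667 and 0.945. The sign for Egr1 turned without placebo animal 1 (-0.22) and without GnRH animal 9 (-0.17).

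**Figure D1:**
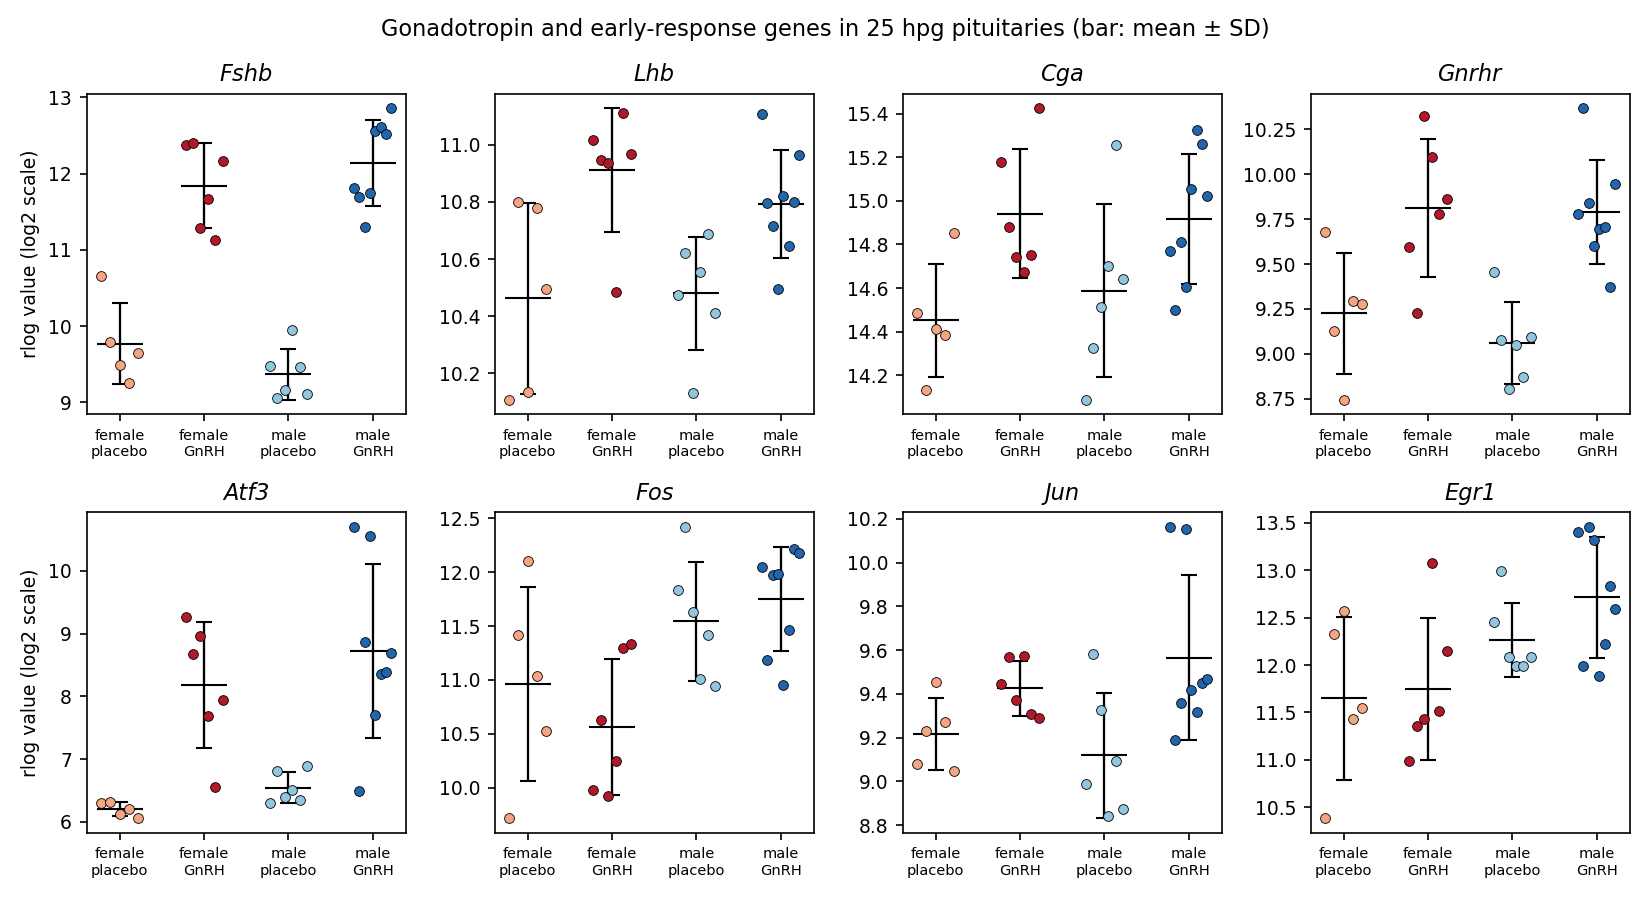
Regularized log2 values of 8 genes in 5 placebo females, 6 GnRH females, 6 placebo males and 8 GnRH males; points are animals, and bars are mean ± SD. Fshb separates the treatments in both sexes, while 2 GnRH animals, female 10 (6.55) and male 19 (6.50), have Atf3 near the placebo values.

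Among the lists in females, 7 of 25 passed camera, all upward, and 0 held with an estimated correlation or with fry. Of the gonadotrope list, 1 of 14 tested members (Fshb) passed over all genes, and 6 higher and 3 lower passed adjusted over the list alone (adjusted p = 0.0455, or adjusted p = 0.507 with an estimated correlation). This list lost its call in 7 of 11 fits, those without placebo animals 1, 2 and 3 and GnRH animals 8, 9, 10 and 11, with adjusted p of up to 0.117. Of 34 immediate early genes 0 passed over all genes with limma and 7 did adjusted over the list alone, and 30 had positive differences (adjusted p = 4.12e-07, or adjusted p = 0.507 with an estimated correlation). The glucocorticoid-responsive list, with 3 of 11 past adjusted over the list alone, had adjusted p = 0.0008 and the endothelial list, with 3 of 8, had adjusted p = 0.000958. Both came to adjusted p = 0.507 with an estimated correlation. The lists of MAP kinase feedback inhibitors (1 of 15 adjusted over the list alone) and macrophage markers (1 of 8) both had adjusted p = 0.0224, and adjusted p = 0.507 and 0.654 with an estimated correlation. Mitochondrial transcripts (0 of 9 adjusted over the list alone, 9 with positive differences) had adjusted p = 0.0101, or adjusted p = 0.735 with an estimated correlation. The feedback list missed the threshold without placebo animal 2 (0.143) and GnRH animals 8 (0.119) and 9, the macrophage list without placebo animals 2 and 4 (0.114) and GnRH animal 9 (0.303), and the mitochondrial list without placebo animal 4 (0.114) and GnRH animal 7 (0.190).

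The AP-1 and ATF list in females (1 of 22 adjusted over the list alone) had adjusted p = 0.0505, and fell under the threshold without placebo animal 3 and GnRH animals 6, 7 (0.0424) and 10 (0.0138). Chga, chromogranin A of secretory granules, rose by 0.40 (adjusted p = 0.0349), but had a difference of 0.19 (adjusted p = 0.523) after quantile normalization and missed the threshold in 7 of 11 fits, those without placebo animals 1, 3 (0.151) and 5 and GnRH animals 6, 7, 8 (0.0533) and 11. The granule list itself, with 1 member past and 2 adjusted over the list alone, had adjusted p = 0.542. The remaining lists were GnRH signalling (adjusted p = 0.242), activin and BMP (0.573), unfolded protein response (0.429), steroid response (0.951), proliferation (0.951), cholesterol synthesis (0.712) and sex-linked genes (0.951). Markers of other cells gave adjusted p = 0.951 for somatotropes, 0.240 for lactotropes, 0.952 for thyrotropes, 0.858 for corticotropes, 0.742 for melanotropes, 0.858 for stem cells, 0.748 for the posterior lobe, 0.454 for pericytes and fibroblasts and 0.748 for blood. Median, mean and test differed in sign for the granule, steroid, somatotrope, thyrotrope and corticotrope lists. Without placebo animal 5, which had the highest mean of the blood list of all libraries (12.94), that list had adjusted p = 0.000756, and without GnRH animal 6 proliferation had 0.0290. The blood list includes globin genes, whose transcripts were depleted during library preparation, so its values may not follow blood content.

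GnRH against placebo in males asked the same question in the other sex. Fshb was 6.81-fold higher, from 9.37 ± 0.33 (SD, n = 6) in placebo to 12.14 ± 0.56 (SD, n = 8) in GnRH males, a log2 difference of 2.77 (SE 0.24, adjusted p = 1.52e-07) with 8 of 8 treated animals above every placebo animal. Atf3 was 4.52-fold higher, from 6.55 ± 0.25 (SD, n = 6) to 8.72 ± 1.39 (SD, n = 8), a difference of 2.18 (SE 0.45, adjusted p = 0.0172) with 7 of 8 treated animals above every placebo animal. Gnrhr rose by 0.73 (SE 0.15, adjusted p = 0.0171), with 7 of 8 animals above every placebo animal. Rrad rose by 2.52 (adjusted p = 0.000991), and Homer1, a synaptic scaffold with an activity-induced short form, by 2.03 (adjusted p = 0.00246). Nr4a3, an orphan nuclear receptor of the immediate early class, rose by 1.44 (adjusted p = 0.0108), and the secreted peptides Npy and Vgf by 1.29 and 1.15 (adjusted p = 0.00648 and 0.0171).

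Nefm, Serpinb1a and Srxn1, an enzyme that restores oxidized peroxiredoxins, rose by 1.25, 1.11 and 1.11 in males, with adjusted p = 0.000173, 0.00204 and 0.0210. In males, 95 genes passed, 86 higher and 9 lower, with 1228 at an unadjusted p under 0.05 and 77 whose groups did not overlap, where chance gives 12.7. Otof, a calcium sensor of vesicle release, fell by 0.99 (adjusted p = 0.00263), Bean1 by 0.53 (adjusted p = 0.0213), the actin-binding gene Aif1l by 0.51 (adjusted p = 0.0160) and Gata2, a transcription factor of gonadotropes and thyrotropes, by 0.50 (adjusted p = 0.0216). Each was below the placebo mean in 8 of 8 treated males. Lhb differed by 0.31 (adjusted p = 0.414), Cga by 0.33 (adjusted p = 0.721), and Fos, Jun and Egr1 by 0.21, 0.45 and 0.45 (adjusted p = 0.999, 0.194 and 0.987). Exact permutation tests of single genes gave p = 0.00932 for Lhb and 0.0320 for Jun in males, and 0.0346 for Lhb, 0.0195 for Cga, 0.0281 for Gnrhr and 0.0476 for Jun in females; adjusted over the 16 such tests they were 0.0249, 0.0554, 0.0554, 0.0445, 0.0554 and 0.0693.

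The count in males was 58, 60, 46 and 63 without placebo animals 12, 13 and 14 and GnRH animal 25, and 153 without GnRH animal 19. Atf3 missed the threshold without placebo animal 12 (adjusted p = 0.0504) or 14 (0.0546), and Gnrhr without 14 (0.0703) or 16 (0.0551). Gata2 missed it without placebo animals 13 (0.0921), 14 and 17 (0.0576) and GnRH animal 18. Bean1, Aif1l, Vgf and Srxn1 lost their calls in 5, 2, 3 and 5 of 14 such fits, with adjusted p of up to 0.0861, 0.0564, 0.0641 and 0.0861, whereas Fshb, Rrad, Homer1, Nr4a3, Npy, Nefm, Serpinb1a and Otof kept theirs in all 14. GnRH animals 18 and 21 had the highest means of the immediate early list (10.43 and 10.46, others 9.25 to 9.73). Without both, a choice made after their values were seen that lowers these genes by construction, 38 genes passed, and Atf3 had 1.54 (adjusted p = 0.0606), Nr4a3 1.09 (0.0522), Vgf 0.81 (0.0592), Srxn1 0.84 (0.129), Aif1l -0.52 (0.0545) and Gata2 -0.37 (0.116).

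In males 8 of 25 lists passed camera, and 3 of them held with an estimated correlation: immediate early genes, AP-1 and ATF subunits, and gonadotrope genes. All 34 immediate early genes had positive differences; 4 passed over all genes, among them Atf3, Nr4a3, Gadd45g (0.46, adjusted p = 0.00774) and Klf10 (0.51, adjusted p = 0.0189), and 23 adjusted over the list alone. The list had adjusted p = 7.21e-32, and adjusted p = 0.0284 with an estimated correlation. Its mean difference was 0.60, and 0.34 without GnRH animals 18 and 21 (list means 10.43 and 10.46, others 9.25 to 9.73), where 31 of 34 were positive, 0 passed over all genes by limma and the list kept its call (adjusted p = 1.13e-18, or adjusted p = 0.00862 with an estimated correlation). Gadd45g and Klf10 also missed the threshold there, both at 0.0606. Klf10 missed the threshold without placebo animals 13 (0.0735), 14 and 17 (0.0565). Of 22 AP-1 and ATF subunits, Atf3 passed and 9 did adjusted over the list alone (adjusted p = 6.25e-08, or adjusted p = 0.0152 with an estimated correlation). Of 14 gonadotrope genes, Fshb, Gnrhr and Serpine2, a protease inhibitor (0.58, adjusted p = 0.000701), rose and Gata2 fell, with 6 higher and 2 lower adjusted over the list alone (adjusted p = 7.6e-05, or adjusted p = 0.0354 with an estimated correlation).

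MAP kinase feedback inhibitors in males (0 of 15 over all genes by limma or adjusted over the list alone, 14 positive) had adjusted p = 3.45e-05, glucocorticoid-responsive genes (3 of 11 adjusted over the list alone, 11 positive) 2.34e-07, and endothelial markers (2 of 8 adjusted over the list alone) 4.34e-05. Each of these came to adjusted p = 0.0704 with an estimated correlation. Emcn, endomucin of endothelium, rose by 0.27 (adjusted p = 0.0416) but missed the threshold in 9 of 14 fits without 1 male, with values of up to 0.119. Of 18 granule genes 3 rose, Vgf, Chga (0.49, adjusted p = 0.000701) and Scg2 (0.67, adjusted p = 0.0209), all 3 also adjusted over the list alone. The granule list had adjusted p = 0.0112, or adjusted p = 0.269 with an estimated correlation, and missed the threshold without placebo animal 15 (0.0846) or GnRH animal 24 (0.0884). Scg2 gave 0.55 (adjusted p = 0.230) after quantile normalization, and missed the threshold without placebo animals 15 and 16 (0.0803) and GnRH animal 25 (0.0571). Cholesterol synthesis moved downward (13 of 16 negative, 0 adjusted over the list alone, adjusted p = 0.00428, or adjusted p = 0.461 with an estimated correlation) and missed the threshold without placebo animal 14 (0.133).

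The other lists in males did not pass. They were GnRH signalling, steroid response, proliferation, macrophages, blood, mitochondrial transcripts and sex-linked genes, each at adjusted p = 0.603, activin and BMP (0.536), unfolded protein response (0.579), somatotropes (0.219), lactotropes (0.794), thyrotropes (0.613), corticotropes (0.223), melanotropes (0.218), stem cells (0.794), the posterior lobe (0.219), and pericytes and fibroblasts (0.465). The median of the unfolded protein response list was negative, and its mean and test were positive. Melanotropes passed without placebo animal 16 (0.0221) and proliferation without placebo animal 14 (0.0285).

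The difference of the GnRH effect between the sexes was tested directly. By limma, 0 of 19141 genes passed, with 529 at an unadjusted p under 0.05 against 957 by chance, and the smallest adjusted p was 0.999. The count was 0 with each alternative run as well. The median SE was 0.0946 for this difference, against 0.0706 for the effect in females and 0.0630 in males. Sex differences are therefore not shown to be absent. Among genes called, 15 rose in both sexes and 0 passed in opposite directions. For independent lists, 0.0854 would be higher in both by chance. Both contrasts share the variance estimate of each gene, so the lists are not fully independent and this number may be too low. The 15 genes include Fshb, Rrad, Nefm, Nefl, Serpinb1a, Scarb1, Timp1, Tnfrsf12a, Cited4 and Chga. Among them are also Vegfa, an endothelial growth factor, and Fdx1, an electron carrier of steroid synthesis, both chosen after their values were seen. In females Fdx1 lost its call in 9 of 11 fits without 1 animal (up to 0.168, without GnRH animal 6), and Vegfa in 3, without placebo animal 5 (0.0714) and GnRH animals 6 and 11 (0.0548). All 95 genes that passed in males had the same sign in females, where 60.6% of all genes tested did, and across all genes the differences correlated at r = 0.56, although genes are not independent replicates. The overlap was 9, 7 and 5 without female placebo animals 1, 3 and 5, 4, 9, 9 and 5 without female GnRH animals 6, 7, 8 and 11, 43 without female GnRH animal 10, and 27 without male GnRH animal 19.

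**Figure D2:**
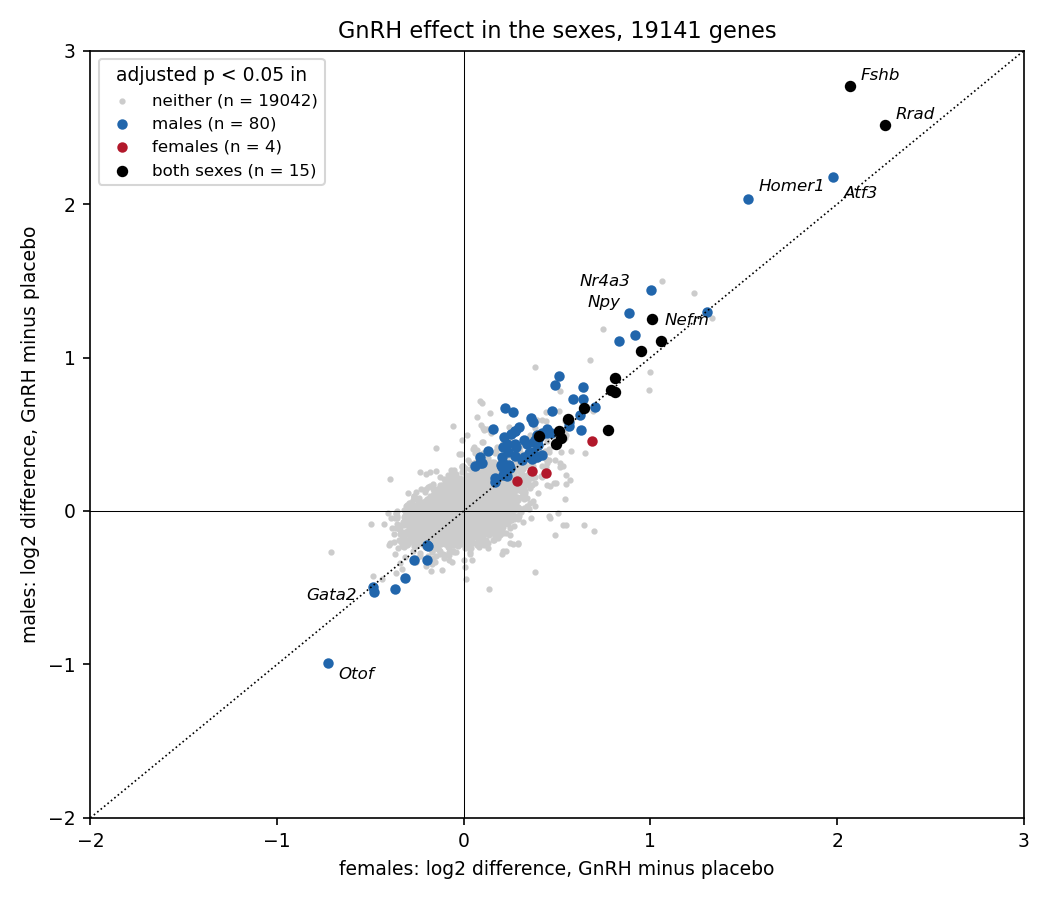
Log2 difference between GnRH and placebo in females (x axis) and males (y axis) for 19141 genes, coloured by adjusted p under 0.05 in neither sex, 1 sex or both; the dotted line marks equal differences. The 15 genes past the threshold in both sexes lie in the upper right, with Fshb at 2.07 and 2.77 and Rrad at 2.26 and 2.52.

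Of 25 lists, 3 differed between the sexes in their response with camera: immediate early genes had larger differences in males (30 of 34 positive, adjusted p = 0.000412), and mitochondrial transcripts (9 of 9 negative, adjusted p = 0.00396) and macrophage markers (8 of 8 negative, adjusted p = 0.00901) less. Each came to adjusted p = 0.671 with an estimated correlation, and 0 genes passed in any of these lists by limma, over all genes or adjusted over the list alone. The immediate early call was lost without male GnRH animals 18 and 21. The mean difference between the sexes was then 0.01 instead of 0.27, with 18 of 34 positive (adjusted p = 0.993). These 2 animals were chosen for their high values of this list, which lowers the difference by construction. The macrophage list had 0.0518 without them. The mitochondrial list lost its call without female GnRH animal 7 (0.120) or male placebo animal 15 (0.137), and the macrophage list without female placebo animal 2 (0.170), female GnRH animal 9 or male placebo animal 15 (0.0991). The other 22 lists had adjusted p from 0.0947 to 0.930, and median, mean and test differed in sign for the glucocorticoid, corticotrope and endothelial lists.

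Leaving out 1 animal brought further lists of this comparison under the threshold. The AP-1 and ATF list passed without female placebo animals 1 (0.0457), 4 (0.0403) and 5 (0.0460) and male GnRH animals 19 (0.0313), 22 (0.0402) and 23 (0.0281). Cholesterol synthesis passed without female placebo animals 1 (0.0457) and 3 (0.0131), female GnRH animal 10 (0.0203) and male placebo animal 16 (0.0195). Melanotropes passed without female placebo animals 1 (0.0457), 3 (0.00635) and 4 (0.0403) and male placebo animal 16. The posterior lobe passed without female placebo animals 3 (0.0131) and 4 (0.0403) and male placebo animal 16 (0.0466), as did pericytes and fibroblasts (0.0207, 0.0403 and 0.0166). Blood passed without female placebo animal 5 (0.0115), proliferation without female GnRH animal 6 (0.00908), and the unfolded protein response without male placebo animal 17 (0.0426) or male GnRH animal 18 (0.0361).

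Averaged over the sexes, 327 genes passed, 272 higher and 55 lower. Fshb rose by 2.42 (adjusted p = 4.55e-09), Atf3 by 2.08 (adjusted p = 0.000638), Gnrhr by 0.66 (adjusted p = 0.00109) and Lhb by 0.38 (adjusted p = 0.0141). Gata2 fell by 0.49 (adjusted p = 0.000638), and was below every placebo animal in 6 of 6 females and 7 of 8 males. Nr5a1 and Foxl2, transcription factors of gonadotropes chosen after their values were seen, fell by 0.38 and 0.30 (adjusted p = 0.0222 and 0.0230), and were below the placebo mean in 5 and 6 of 6 females and 7 and 8 of 8 males. Nr5a1 missed the threshold without female placebo animal 4 (0.0571), and Foxl2 without female placebo animals 1 (0.0543) and 4 (0.0589). Cga had a difference of 0.41 (adjusted p = 0.0707), under the threshold without female placebo animal 5 (0.0434), male placebo animal 16 (0.0135) or male GnRH animal 19 (0.0390). Jun had 0.33 (adjusted p = 0.114), under it without male placebo animal 13 (0.0496), and Fos and Egr1 had -0.09 and 0.27 (adjusted p = 0.903 and 0.692). The sign for Fos turned without female placebo animal 3 (0.05).

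Males against females served as a check of the labels and of the scale. In placebo animals 9 genes passed, 6 higher and 3 lower in males. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were higher in males by 3.29, 3.18, 3.07 and 2.38, and Xist, the RNA that silences an X chromosome in females, was lower with a difference of -5.71. Kdm6a and Kdm5c, X-linked genes that escape silencing, differed by -0.53 and -0.40 (adjusted p = 0.00602 and 0.00716), and Kdm5c missed the threshold without female placebo animal 1 (0.0561). The other 2 were predicted genes. Female Eif2s3y values of 6.47 ± 0.11 (SD, n = 5), for a gene females lack, show how far the regularized scale holds absent transcripts above 0, and reads shared between Y and X copies leave these values uncertain.

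In GnRH animals 10 genes passed between the sexes, 6 higher and 4 lower in males. Eif2s3y, Ddx3y, Kdm5d and Uty were higher by 3.08, 3.07, 2.91 and 2.30, and Xist, Kdm6a and Kdm5c differed by -5.77, -0.49 and -0.32. Pbdc1, an X-linked gene, differed by -0.38 (adjusted p = 0.0223). Pbdc1 missed the threshold without female GnRH animals 6 (0.113), 10 and 11 and male GnRH animals 18, 19, 21 and 22, and Kdm5c without female GnRH animals 8 (0.126) and 9 and male GnRH animals 18, 19, 20, 22 (0.0543) and 24. The count was 17 without female GnRH animal 10. No sex difference passed for Fshb (-0.40 in placebo, 0.30 with GnRH) or Atf3 (0.34 and 0.54), with adjusted p = 0.999 and 0.935 for both.

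Of the lists, 2 passed between the sexes in placebo animals: cell cycle genes were lower in males (18 of 20 negative, 0 adjusted over the list alone, adjusted p = 6.45e-05, or adjusted p = 0.816 with an estimated correlation), and sex-linked genes differed (7 of 9 past, 9 adjusted over the list alone, adjusted p = 0.000252, or adjusted p = 0.466 with an estimated correlation). The other 23 had adjusted p from 0.0733 to 0.993. Of these, melanotropes passed without female placebo animals 1 (0.0225), 3 (0.000639) and 4 (0.0123) or male placebo animal 16, and blood without female placebo animal 5 (0.000675). With GnRH, 8 passed. Immediate early genes (6 of 34 adjusted over the list alone, adjusted p = 3.01e-10) and AP-1 and ATF subunits (2 of 22 adjusted over the list alone, 0.0183) were on the male side. Sex-linked genes differed (4 higher and 3 lower over all genes, 4 higher and 5 lower in males adjusted over the list alone, adjusted p = 0.000186). These 3 lists each came to adjusted p = 0.426 with an estimated correlation. Mitochondrial transcripts (adjusted p = 4.6e-05), macrophages (0.000153), proliferation (0.00121), pericytes and fibroblasts (0.00997) and cholesterol synthesis (0.0183) were on the female side, with 1 member past adjusted over the list alone, in the macrophage list. These came to adjusted p = 0.446, 0.426, 0.634, 0.446 and 0.712 with an estimated correlation. Median, mean and test differed in sign for the sex-linked list in both sex contrasts. They also did so for the AP-1 and ATF, granule, glucocorticoid, thyrotrope, corticotrope, macrophage and mitochondrial lists in placebo, and for the steroid and melanotrope lists with GnRH.

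Without 1 or 2 animals some of these calls ended. Without male GnRH animals 18 and 21 the immediate early list had a mean difference of 0.12 instead of 0.37 (adjusted p = 0.189), and the AP-1 and ATF list had adjusted p = 0.688. These 2 animals were chosen for their high values of the immediate early list, which lowers that difference by construction. The AP-1 and ATF list missed the threshold without female GnRH animal 10 (0.129) and male GnRH animals 18 (0.0718) and 21, proliferation without female GnRH animal 6 (0.662), pericytes and fibroblasts without female GnRH animals 6 (0.0821) and 8 (0.0637) and male GnRH animal 24, and cholesterol synthesis without female GnRH animals 6 (0.0685), 8 (0.421) and 9 and male GnRH animals 19 and 24. The other 17 lists had adjusted p from 0.0565 to 0.991. Of these, granule genes passed without female GnRH animal 9 (0.00870) or male GnRH animals 18 (0.0129), 21 (0.0192) and 23 (0.0456), and the unfolded protein response without male GnRH animals 18 (0.0135) and 21 (0.0413).

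Relations between genes across treated animals asked whether animals with more Atf3 also have more Fshb. Atf3 (ENSMUSG00000026628) lies on chromosome 1 from 191170296 to 191218039 of mm10, on the minus strand, with 3 annotated transcripts of up to 5 exons. Fshb (ENSMUSG00000027120) lies on chromosome 2 from 107056140 to 107059656, on the minus strand, with 1 transcript of 3 exons. Over 6 GnRH females r was 0.58 (exact permutation p = 0.226, rho 0.54, p = 0.297), and without animals 6 and 10, farthest from the median of Atf3, it was -0.17. Over 8 GnRH males r was -0.23 (exact permutation p = 0.585, rho -0.19, p = 0.665), and -0.56 without animals 18 and 19. Leaving out the 2 animals farthest out narrows the range of the first gene by construction. It also leaves 4 females or 6 males, so these values cannot decide whether 2 animals carry a relation. Of the 12 relations computed 0 passed after adjustment, the smallest adjusted p for r being 0.679. The smallest unadjusted exact permutation p was 0.0778, for Egr1 and Lhb in females (r = -0.85, rho -0.37, and 0.13 without animals 9 and 11). With 6 and 8 animals only very strong relations could pass, so relations are not shown to be absent. All values come from 1 time point, so relations at other times were not examined.

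**Figure D3:**
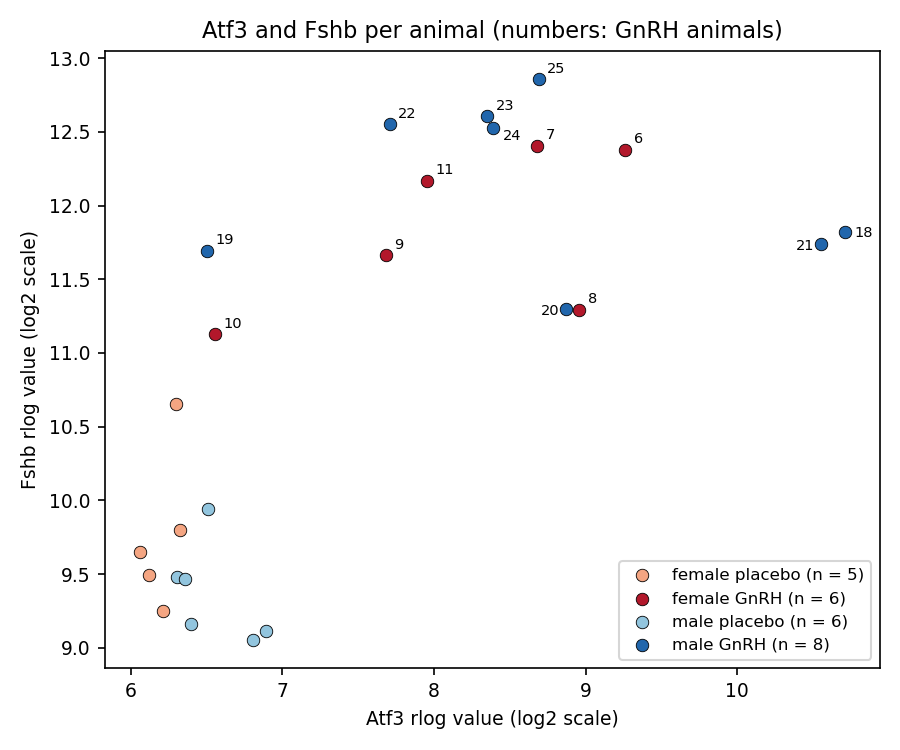
Atf3 (x axis) and Fshb (y axis), both in regularized log2 values, for each of 25 animals, with numbers beside the GnRH animals. Male 19 (Atf3 6.50, Fshb 11.69) and female 10 (6.55, 11.13) have Atf3 near the placebo values and Fshb above every placebo animal of their sex, the highest of which are 9.94 and 10.65.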

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

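The tests of mislabelling, gonadotrope numbers, thyrotropes and the 2 GnRH males 18 and 21 in this part were chosen only after the result was seen, and those of mislabelling and gonadotrope numbers were also revised after their first values were seen; those of scaling, list correlation, single animals and splits were written before.

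Single values far from the rest of their group were found for 14 of 240 combinations of 60 genes and 4 groups, where 12 would be expected at 1 in 20. Of these, 4 lay in male GnRH animal 19, each the lowest of its group: Nefm (9.12), Klf10 (9.22), Spp1 (7.34) and Vegfa (10.20). The mean of posterior lobe markers in this animal was 7.00, against 7.35 to 7.83 in the other GnRH males, and female placebo animal 2 had 6.81, with 9.80 for melanotrope markers. Female GnRH animal 9 was lowest for Lhb (10.49) and Mt2 (10.60), and female GnRH animal 10 was lowest for Rgs2 (10.33) and highest for Nr5a1 (10.07). The other 6 were Aif1l in female GnRH animal 6 (6.83), Kdm5c in male placebo animal 17 (10.88), Eif2s3y in female placebo animal 5 (6.67), Xist in male placebo animal 15 (8.89), Gadd45b in male placebo animal 14 (8.15) and Npas4 in female placebo animal 2 (9.67). The GnRH effect differed between the sexes in the immediate early (adjusted p = 0.000412), mitochondrial (0.00396) and macrophage (0.00901) lists with camera at the preset correlation. Each of these calls was lost, at adjusted p = 0.671 with an estimated correlation.

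In female GnRH animal 10 and male GnRH animal 19 Atf3 lay near the placebo level; the design names no biological explanation to test, and only technical ones were weighed. A placebo animal labelled as GnRH-treated is argued against for male 19, whose Fshb was 6.97 placebo SD above the placebo mean. For female 10, at 2.54, it stays open because its values go both ways. Fshb, Atf3 and the mean of Gnrhr, Cga and Lhb (0.50 above the placebo mean, placebo SD 0.17) exceeded every placebo female. So did 114 of 321 genes raised in the fit without female 10. In male 19, 106 of 290 such genes exceeded every placebo male. No share by chance was computed. The median position of female 10 from placebo to GnRH was 0.211, below the highest placebo female (0.219). It covers genes called in the averaged contrast without the animal, at an absolute log2 difference of at least 0.25. Members of the immediate early, AP-1 and ATF, and MAP kinase feedback lists were left out. With 1 time point, when these genes respond is unknown. The bound of 5 placebo SD was set after these distances were seen, following 2 earlier forms of the test: the first put both animals above every placebo animal of their sex, and the second put male 19 at 0.306 against a highest placebo male of 0.256. Fewer gonadotropes in the tissue are argued against, since the mean of Gnrhr, Cga and Lhb differed from the other GnRH animals by -0.00998 in female 10 and 0.06 in male 19, where Atf3 differed by -1.95 and -2.54; a late or failed last injection was not tested.

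Gata2, Nr5a1 and Foxl2 fell while Fshb, Gnrhr and Lhb rose. Fewer gonadotropes after GnRH are argued against, as 8 of 8 tested members of the list outside these 6 genes had intervals wholly above the mean difference of the 3 that fell (-0.39), though induction within each cell could hide a loss of cells. Scaling between libraries is argued against by a highest adjusted p of 0.0270 after median shifting and quantile normalization. Fewer thyrotropes are argued against by the lower limit of -0.22 for the mean of 4 thyrotrope genes, against -0.40 for Gata2 and Foxl2. A fall within gonadotropes may be the explanation left among those weighed, but no single-cell values were analysed here.

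The immediate early list had larger differences with GnRH in males than in females. The means of the list were 10.43 and 10.46 in male GnRH animals 18 and 21 and 9.25 to 9.73 in the other 6 GnRH males. Without these 2 animals the adjusted p was 0.993 and the mean difference between the sexes 0.01. They were chosen for their high values, which lowers the difference by construction, so this fit cannot decide whether they carry it. The call was kept when 1 animal was left out at a time, the highest adjusted p over 25 fits being 0.0374. Correlation between list members fits, since the adjusted p was 0.671 with an estimated correlation. A sex difference, as the biological explanation, is not shown by these values and stays untested beyond them.

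Splits of the same samples into other groups, the real one counted, gave at least as many genes in 4 of 100 for females (real 19, highest other 3515) and 1 of 100 for males (real 95, highest other 54). For the averaged effect it was 2 of 100 (real 327, highest other 540), for sex in placebo 3 of 100 (real 9, highest other 13) and for sex with GnRH 3 of 100 (real 10, highest other 1087). For the difference between sexes the real count was 0 (highest other 1536), so 100 of 100 splits reach it by construction and the comparison tests nothing. Other splits with 3515, 1087 and 1536 genes call many times more than the real ones, which points to a structure of the samples. What that structure follows was not tested.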

How the results depend on the processing

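The covariate for the largest axis within groups, the fits without libraries far out on it and the fit without male GnRH animals 18 and 21 were chosen only after the result was seen; the other alternatives were planned.

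Fshb kept its call in both sexes under every alternative, with ranges of 1.94 to 2.29 in females and 2.66 to 2.89 in males when 1 library was left out, and the count of genes that differ between the sexes in their response stayed at 0. The 28 list calls became 3 with an estimated correlation and 5 with fry, and 24 to 34 without 1 library. Depth is unknown, and shrinkage understates the differences of low genes, so a gene that missed the threshold is not shown to be unchanged.

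Without a filter on low values, which adds genes to the adjustment, counts were 7 in females (from 19), 42 in males (from 95) and 5 in both (from 15). With array weights they were 62, 239 and 942 (females, males and averaged over the sexes, from 327), the latter 546 higher and 396 lower. The weights were estimated from the same values as the fit, and the lowest was 0.34, in female GnRH animal 9. These weighted counts are therefore no independent check, and the cause of their rise was not tested. With the largest axis within groups as covariate they were 423 (218 higher and 205 lower), 156 and 923, and 21 for sex with GnRH (from 10). That axis comes from the residuals of the same fit, so it shrinks the spread by construction and these counts are not a fair test. Asking for a log2 difference of at least 1 as well left 4, 12 and 13, and 6 for sex with GnRH, as fewer genes can meet it.

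Atf3 in males had 2.18 with adjusted p = 0.0691 without the filter and 0.0610 with the robust variance model, and a range of 1.89 to 2.49 without 1 library. Without male GnRH animals 18 and 21, which had the highest Atf3, it had 1.54 (adjusted p = 0.0606), and 38 genes passed in males with fewer samples. Calls of Cited4 (0.48, adjusted p = 0.0606), Scg2 (0.68, 0.0694) and Emcn (0.23, 0.226) in males, of Pbdc1 (-0.34, 0.206) and Kdm5c (-0.33, 0.106) for sex with GnRH, and of Foxl2 averaged over the sexes (-0.26, 0.054) were lost in that fit too, while the list calls went from 28 to 32. Atf3 in females had 1.98 with adjusted p = 0.0355 with the covariate of the largest axis, p = 0.00433 by exact two-sided permutation (6 and 5 animals, unadjusted), and a range of 1.76 to 2.30. The gonadotrope list in females had adjusted p = 0.0752 at a mean of at least 5, 0.0508 after quantile normalization, 0.507 with an estimated correlation, 0.279 with fry and 0.0583 with the covariate, and ranged from 0.0181 to 0.117 without 1 library. The immediate early list in females had 0.507 with an estimated correlation and 0.349 with fry. The AP-1 and ATF list in females had 0.0452 without the filter, 0.0455 at a mean of at least 5, and ranged from 0.0138 to 0.191 without 1 library. The cause was not tested for these changes.

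Without 1 library counts ranged from 4 to 67 in females, 46 to 153 in males, 4 to 43 in both, 8 to 17 for sex with GnRH, 7 to 9 for sex in placebo and 235 to 389 averaged over the sexes. The sign for Egr1 in females turned without female placebo animal 1 (-0.22) and without female GnRH animal 9 (-0.17), which is also the fit without libraries beyond 2 SD on the largest axis, and its range without 1 library was -0.22 to 0.33. Fos averaged over the sexes turned to 0.0487 without female placebo animal 3, with a range of -0.25 to 0.0487. The r of Egr1 and Lhb in GnRH males turned to -0.000137 after median shifting. The cause was not tested for these reversals.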

Other observations

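No test in this part was chosen only after the result was seen, and the genes named were chosen after their values were seen.

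Averaged over the sexes, Arc, a cytoskeletal gene of active neurons, rose with GnRH by 1.33 (adjusted p = 0.0139). The AP-1 subunit Fosb rose by 1.28 (adjusted p = 0.0125), and Gadd45b, a stress-induced signalling gene, by 0.56 (adjusted p = 0.00321). They were picked among genes that passed, while Fos, Jun and Egr1 did not pass in this contrast. No list test is given for this averaged contrast, so no rise of such genes as a class is shown in it. Within each sex, the immediate early list passed camera upward, and it held with an estimated correlation in males only. Arc was above the placebo mean in 6 of 6 females and 8 of 8 males, Fosb in 5 and 8, and Gadd45b in 6 and 8. Spp1, osteopontin, rose by 0.95 (adjusted p = 0.0107; 5 of 6 and 7 of 8), Serpine2 by 0.48 (adjusted p = 6.6e-05; 6 of 6 and 8 of 8), and Cdkn1a, an inhibitor of the cell cycle, by 0.50 (adjusted p = 0.00388; 6 of 6 and 8 of 8).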
